A study of Homo sapiens with 13 samples.

How the data were processed

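Guide RNA cassettes were amplified by PCR from genomic DNA of the surviving cells, barcoded and sequenced as single-end reads of 300 nt, per the labels' protocols. These protocols state that the infected population held at least 500 cells per guide on average and that puromycin selection lasted 96 h. The read counter and the normalisation formula are not given in the sources used here.

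The deposited table holds log2 values for 77441 guides of 20 bases in 13 columns. What the authors computed was worked out from the low values. In each ML210 column the smallest values equal log2(1 + s)/3 and log2(1 + 2s)/3 to within 3e-08, where s is the worth of 1 read in RPM (reads per 1000000 reads), and of the divisors from 1 to 60 the only one with such matches was 3. In the DMSO column, named only as a control, the divisor was 26, and 14 step sizes were found. It was taken as the 1 DMSO sample of the labels. The deposited log2 values are therefore taken as log2(RPM + 1), with a pseudocount of 1, averaged over 3 or 26 separately sequenced measurements. The step sizes give the reads per measurement, 569000 to 1576000 in ML210 libraries and 1101000 to 1668000 for DMSO. Averaging logs lowers a guide that was missed in some measurements, so linear totals of the columns ranged from 250818 to 894611, below 1000000. Averaging over 26 measurements also makes DMSO values smoother than ML210 values and leaves fewer guides at 0. The table gives no whole read counts. Those of guides read in 1 or 2 measurements of an ML210 library can be worked out from the step sizes. Those of guides read in all 3 were not, and for DMSO only 14 of 26 step sizes were found, so no test for counts was run. For each ML210 value, the number of measurements with a read was decoded from the step sizes, which was correct for 99.7% of 60000 simulated values.

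The design fixed before the data were examined assumed values that could be joined to genes. The table names no gene and no genome was used here, so gene values, the test of agreement between guides of a gene, the 28 gene lists, the check on non-targeting guides and the median over guides were not run, and the planned limma fit was made on guides. No gene named in advance could be looked up. Guides with a mean log2 value of at least 1 over the 13 libraries were kept (38067), and each library was centred on its median, which ranged from 0 to 2.266. Values per library and their means ± SD are as deposited, and fitted differences are on the centred log2(value + 1) scale, which understates changes of low guides. The DMSO median was the highest, so centring raises every change against DMSO above the difference of the deposited values. The fit by limma 3.58.1 in R 4.3.3 had 7 groups, residual df 6 and prior df 14.01, with Benjamini-Hochberg adjustment at 0.05. It used the spread within the 6 duplicates for the single DMSO library too. Contrasts were the mean of the 6 fatty acid groups against DMSO, each acid against DMSO, an F-test among the acids, C18 against C20 and C22 acids, and 4 pairs of acids of related structure. Contrasts against DMSO share that library, so their estimates have common chance values and their overlap was not tested. On 38067 simulated guides with a noise SD of 0.3 the fit recovered 100% of guides changed by 2 or more on the log2 scale in the contrast against DMSO. At the real noise SD of 1.763 it recovered 0%, 4%, 22% and 62% of those changed by 2, 4, 6 and 8, with 3 false calls.

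The rule for naming guides, set before the data were examined, takes called features and, for contrasts among acids where none is called, those of smallest p. The recurrent guides and the 2 pooled falls were chosen after their values were seen. Recurrence was counted over all 77441 guides. Guides were put into 20 strata of DMSO value, the top 1% of each stratum was marked in each ML210 library (760 guides per library), and the number of libraries was tested against a binomial distribution with Benjamini-Hochberg adjustment, in Python 3.11.15 with SciPy 1.17.1. On 77441 guides shuffled within strata, this recovered 18%, 80%, 100% and 100% of guides planted at the top of 20%, 40%, 60% and 80% of libraries, with 1 false call. Each library was shuffled separately, which makes libraries independent, so that false call count does not cover dependence between the real libraries. Guides in the top 1% of at least 6 of 12 libraries are named by number and sequence. Means of these guides were compared between acids by exact permutation of libraries.

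Alternatives fixed in advance were pseudocounts of 0.5 and 10, no filter, a filter at the 5th percentile of DMSO, no centring, scaling to equal totals, the replicate letter as a block and each ML210 library left out in turn. Added after seeing the data were DMSO as a fixed reference, the fit without both EPA B and DHA B, the alternatives to the recurrence test, and pairings of A with B libraries.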

Results

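A pooled CRISPR knockout screen asked which guide RNAs were carried by UACC257 melanoma cells that outlived ML210 after exposure to a polyunsaturated fatty acid. UACC257 is a human melanoma line and expressed Cas9 here, and ML210 inhibits GPX4, the peroxidase that removes lipid hydroperoxides and thereby holds back ferroptosis. The cells received the Brunello library of 77441 guides and were kept with a fatty acid for 3 days before 5 µM ML210 was added. The data comprised 13 libraries, 1 from cells given DMSO and 2, lettered A and B, from ML210-treated cells for each of 6 fatty acids. These were C18:2 (18 carbons and 2 double bonds), C18:3 (18 and 3), C20:4 (20 and 4), eicosapentaenoic acid (EPA, 20 and 5), docosapentaenoic acid (DPA, 22 and 5) and docosahexaenoic acid (DHA, 22 and 6). The doses of the fatty acids were not in the labels, so the acids are set side by side without knowledge of whether the doses matched. By its label the DMSO library had neither ML210 nor a fatty acid, so a comparison with it cannot separate the effects of these. The control column averages 26 measurements while the labels list 1 DMSO sample, and the cultures behind them are not stated. If they include controls given a fatty acid without ML210, the comparisons with DMSO mean something else.

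Each value was the mean over separately sequenced measurements of log2(RPM + 1), where RPM is reads per 1000000 reads of a measurement, with 3 measurements behind each ML210 library and 26 behind the DMSO library. Total reads behind an ML210 library ranged from 1930000 in C20:4 A to 4180000 in DHA A. A guide listed at 0 in an ML210 library could have had up to 0.72 to 1.55 RPM over its 3 measurements, the range over libraries of the worth of 3 reads. This limit covers counting error only, since reads of PCR products are not independent molecules. The files pair guides with no gene, so guides are reported by their sequence.

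Columns differed in the number of guides above 0 and in how many measurements they averaged, and a guide has more chances to be read in more measurements. In the DMSO library, the mean of 26 measurements, 98.58% of the 77441 guides were above 0, and its 1% most abundant guides held 7.2% of the linear total. In the ML210 libraries, each the mean of 3, between 21.21% (DHA B) and 62.56% (EPA A) of guides were above 0, and the top 1% held between 13.79% (EPA A) and 71.89% (DHA B). EPA B was close to DHA B, with 21.96% of guides above 0 and 56.99% of its total in the top 1%. The other library of each of these acids was broad, with 62.56% of guides above 0 in EPA A and 58.58% in DHA A. Averaged over all 12 ML210 libraries (36 measurements), 96.99% of guides were above 0 and the top 1% held 9.5%. Over sets of 9 libraries (27 measurements), 92.72% to 96.32% were above 0. Such pooling joins acids and libraries as well as measurements. It cannot separate the number of measurements from guides lost in single libraries. The percent above 0 therefore cannot be compared between DMSO and a single ML210 library. The mean log2 value of a column, which does not depend on the number of measurements averaged, was 1.709 for DMSO and 0.393 to 1.613 for the ML210 libraries. In total, 2331 guides were at 0 in all 12 ML210 libraries and 250 were above 0 in all 12. Of the 7745 guides with the highest DMSO values, 0 were at 0 throughout.

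**Figure D1:**
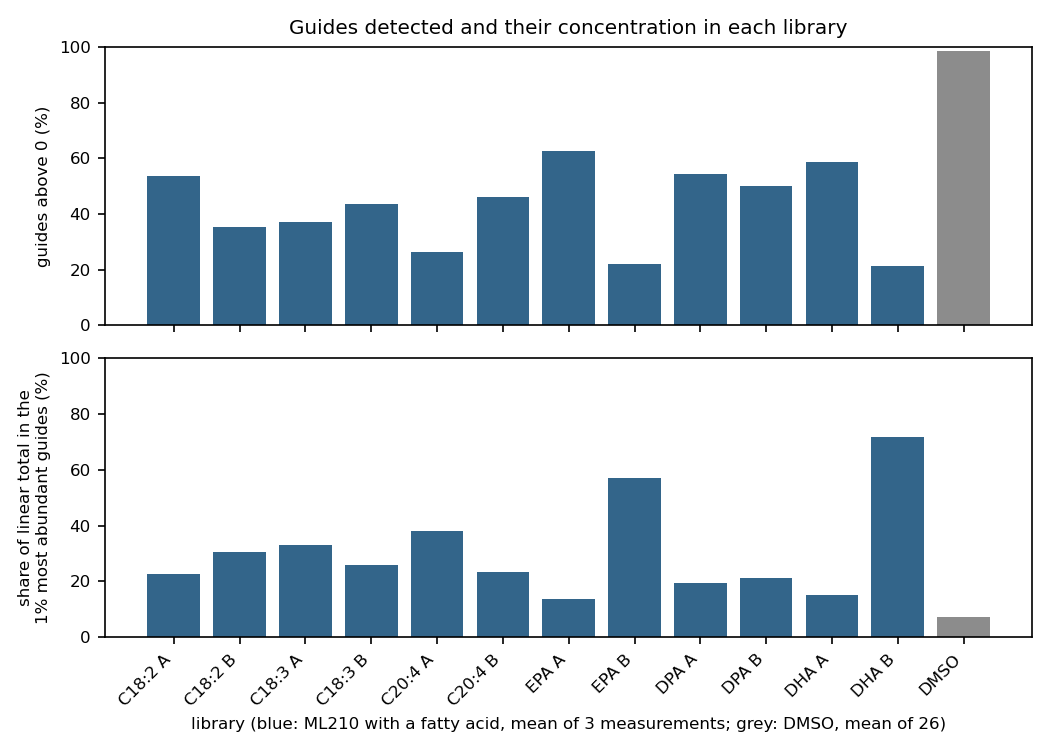
Bars give, for each library on the horizontal axis, the percent of the 77441 guides above 0 (upper panel) and the percent of the linear total held by the 1% most abundant guides (lower panel), in blue for ML210 (mean of 3 measurements) and grey for DMSO (mean of 26, so not comparable in height). Among ML210 libraries, EPA B and DHA B have the fewest guides, 21.96% and 21.21%, and the highest shares in the top 1%, 56.99% and 71.89%.

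The median correlation between libraries of the same fatty acid was not above that between libraries of different acids. Over guides, which are not independent replicates, Pearson's correlation lay between 0.082 and 0.214 for the 6 same-acid pairs (median 0.13) and between 0.048 and 0.275 for the 60 pairs of different acids (median 0.158; 0.156 for the 30 of these with different letters, as the same-acid pairs have). With the DMSO library, smoothed by its 26 measurements, it lay between 0.139 and 0.433 (median 0.353). Between 50.88% and 72.46% of the guides above 0 in an ML210 library had been read in only 1 of its 3 measurements. No 2 libraries held identical values. The labels do not say that A and B came from separate cultures, so all p-values measure the spread between these libraries, which may be technical.

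The first comparison asked which guides were more abundant after ML210 with any fatty acid than in DMSO. A small set of guides was high in library after library. Guide 1, AACTTGCCATCAACCCACTG, averaged 8.91 ± 2.18 (SD, n = 12) over the ML210 libraries against 2.89 in DMSO and was above its DMSO value in 12 of 12. Guide 2, AGAGGCGAGTGATTTGACTG, averaged 7.30 ± 3.63 (SD, n = 12) against 0.67, again higher in 12 of 12, and guide 3, ACTGCGGGACGAAGAGCTCG, averaged 7.0 ± 3.14 (SD, n = 12) against 1.40, higher in 11. Guide 4, ACGGATTCTTGGCATCAAAG, averaged 6.90 ± 1.86 (SD, n = 12) against 1.93 and was higher in 12 of 12 libraries. The falls of smallest p were those of TGTACCTGGCCACAATGCTG, at 0.79 ± 1.55 (SD, n = 12) against 4.78, and GCTCCAAGTTCACGGCGGTG, at 1.17 ± 1.67 (SD, n = 12) against 5.06.

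In the limma fit of 38067 guides, the change against DMSO was 7.12 on the log2 scale (SE 1.98) for guide 1, 7.73 (SE 2.33) for guide 2, 6.70 (SE 2.13) for guide 3 and 6.07 (SE 1.78) for guide 4. For TGTACCTGGCCACAATGCTG it was -2.88 (95% interval -6.51 to 0.76), and for GCTCCAAGTTCACGGCGGTG it was -2.79 (-6.47 to 0.90). None of these passed, and limma's smallest adjusted p was 1 in each direction: 0 guides were enriched and 0 depleted, with 11 and 0 at an unadjusted p under 0.05 (17 and 0 without C18:2 A or without C20:4 B). With a pseudocount of 10 the unadjusted counts were 10 and 16, and with no filter 27 and 8. All are far below the share of 0.05 of guides tested that chance alone would give. The fit is thus too cautious, and its 0 calls do not show that guides were unchanged. It lets the single DMSO library vary as an ML210 library does, with a median residual SD of 1.763. With that noise, the fit recovered 22% of simulated guides changed by 6 on the log2 scale and 62% of those changed by 8. Centring adds to each change against DMSO, since the median was 2.266 for DMSO and 0 to 2.009 for ML210 libraries. Rises in this fit are therefore larger, and falls smaller, than between the deposited values.

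A fit that took the DMSO values as a fixed reference was added after seeing the data. They average 26 measurements, but of unstated cultures that may pool several kinds of control, so a small error of the mean is an assumption. It called 420 guides enriched and 49 depleted. All 10 guides in the next paragraph were among the enriched, and guide 1 had a limma adjusted p of 1.3e-06. TGTACCTGGCCACAATGCTG, with an adjusted p of 0.013, was among the depleted and below its DMSO value in 12 of 12 libraries. The 49 depleted guides lay at or above percentile 97.7 of DMSO values, and the 420 enriched guides had a median percentile of 22.6. That split follows in part from the construction. Guides were kept on their mean over 13 libraries, 12 of them ML210, so 1 with a very low DMSO value was kept only if higher with ML210. Values cannot fall below 0, so only guides high in DMSO can fall far, and centring raises every change. This fit leaves out the spread of the DMSO library itself, and on simulated unchanged guides it called 0 in either direction when the DMSO value had no error, but 10217 enriched and 10264 depleted when it varied like an ML210 library. The latter numbers are far above the 420 and 49 called in the data, and no DMSO error between these settings was simulated. How many of the 420 and 49 are false calls is therefore not known.

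A test that does not rest on the spread of the DMSO library, also added after seeing the data, counted in how many ML210 libraries a guide was in the top 1% among guides of like DMSO value. Of 77441 guides, 27 were recurrent (binomial test, Benjamini-Hochberg adjusted p under 0.05), each in the top 1% of at least 4 of 12 libraries, where independent libraries would give 0.36 such guides. Of these, 10 reached at least 6 libraries, where 6.8e-05 would be expected for independent libraries. If libraries share cultures or handling, which the labels do not say, these expected numbers and the binomial p-values are too small. Guides 1 and 2 were in the top 1% of 10 libraries (adjusted p = 2.5e-14) and guides 3 and 4 of 9 (adjusted p = 4.1e-12). Guide 5, CCTGCATTCTGCCTTAGTCA, was in the top 1% of 8 libraries (adjusted p = 7.4e-10) and averaged 6.19 ± 3.30 (SD, n = 12) against 2.63 in DMSO.

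Guides 6 to 9 were each in the top 1% of 7 libraries (adjusted p = 6.5e-08). They were ACTGTACTGACTCACCCCTC at 6.94 ± 2.84 (SD, n = 12) against 2.74 in DMSO, ACATGCCTCGCATCCCGTAG at 6.89 ± 1.98 (SD, n = 12) against 2.62, GTGGTCCCCAGATTCATACC at 6.38 ± 2.77 (SD, n = 12) against 2.40 and TCGTACAGCACGTTGGTACG at 5.34 ± 3.34 (SD, n = 12) against 1.57. Guide 10, GTGTGTCTGAGGAGATAGCG, was in the top 1% of 6 libraries (adjusted p = 6.8e-06) and averaged 6.08 ± 3.24 (SD, n = 12) against 2.44. In DMSO the 10 guides ranged from the 14.8th to the 86.4th percentile of all guides, with 3 at or below the median. The other 17 recurrent guides were in the top 1% of 4 or 5 libraries. With a null that lets guides differ in their chance of being in the top 1%, 17 of the 27 passed, the 10 named guides among them. Without strata of DMSO value the count of recurrent guides was 57.

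**Figure D2:**
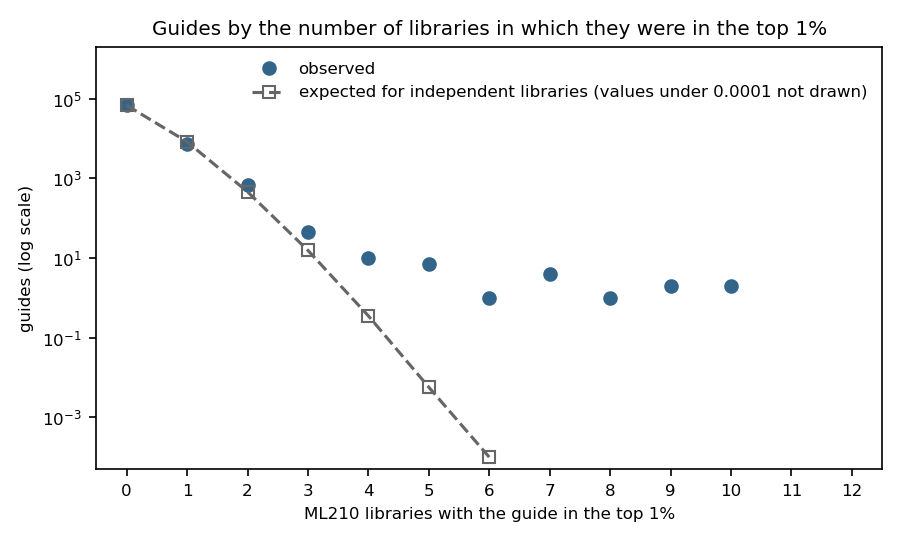
Points give the number of guides (log scale) found in the top 1% of 0 to 12 ML210 libraries, and open squares the number expected if the libraries were independent. Up to 1 library the points and squares lie close together, while 10 guides were in the top 1% of at least 6 libraries against 6.8e-05 expected. At 2 and 3 libraries, 682 and 45 guides were observed against 462.2 and 15.6 expected.

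The second question was whether the fatty acids differed in the guides that survived. The 10 named guides were highest on average with C18:3, at 9.33 ± 0.46 (SD, n = 2). Their mean was 7.55 ± 1.27 (SD, n = 2) with DPA, 6.60 ± 1.64 (SD, n = 2) with DHA, 6.54 ± 1.44 (SD, n = 2) with C20:4, 5.92 ± 2.25 (SD, n = 2) with C18:2 and 4.82 ± 4.33 (SD, n = 2) with EPA. It was 2.13 in DMSO. The low EPA mean came from EPA B, where the 10 guides averaged 1.76 and 0 of them were in the top 1%, against 7.88 and 10 of 10 in EPA A. For these guides, differences among the acids did not exceed the spread within duplicates, an SD of 2.25. Exact permutation over the 10395 pairings of the 12 libraries gave a one-sided p of 0.5026, and over the 720 pairings of an A with a B library 0.5375. The guides were chosen for being in the top 1% of at least 6 of 12 libraries. A guide high with 1 acid alone, which has 2 libraries, could not be among them. This test and the comparisons of named guides below therefore bear only on widely shared guides. They do not show that the acids were alike in other guides.

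Against DMSO, guide 1 changed by 10.46 on the log2 scale with C18:3 (95% interval 5.61 to 15.32) and guide 2 by 12.41 (6.68 to 18.14). With C18:2 the estimates were 6.97 (2.11 to 11.82) for guide 1 and 8.65 (2.92 to 14.38) for guide 2. The largest estimate with DHA was that of guide 10, 9.39 (3.90 to 14.89). None passed limma's adjusted threshold: 0 guides were enriched with any single acid, with 149 at an unadjusted p under 0.05 for C18:2, 321 for C18:3, 337 for C20:4, 350 for EPA, 44 for DPA and 359 for DHA. Each of these unadjusted counts is far below the share of 0.05 of guides that chance alone would give over both directions. They do not rank the acids, since they moved with the libraries, the filter, the centring and the pseudocount. In the same order they were 11, 35, 36, 66, 16 and 133 without centring. With a pseudocount of 10 they were 360, 542, 383, 395, 313 and 338. Without the A library of the acid they were 1759 for C18:2, 522 for C18:3, 2592 for EPA, 295 for DPA and 2047 for DHA. Without its B library they were 1776 for C18:3, 3258 for C20:4, 80 for EPA, 91 for DPA and 121 for DHA. With no filter on guides DPA had 1582, EPA 430 and DHA 376. With DMSO as a fixed reference, C18:3 had 10 enriched guides and every other acid 0.

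**Figure D3:**
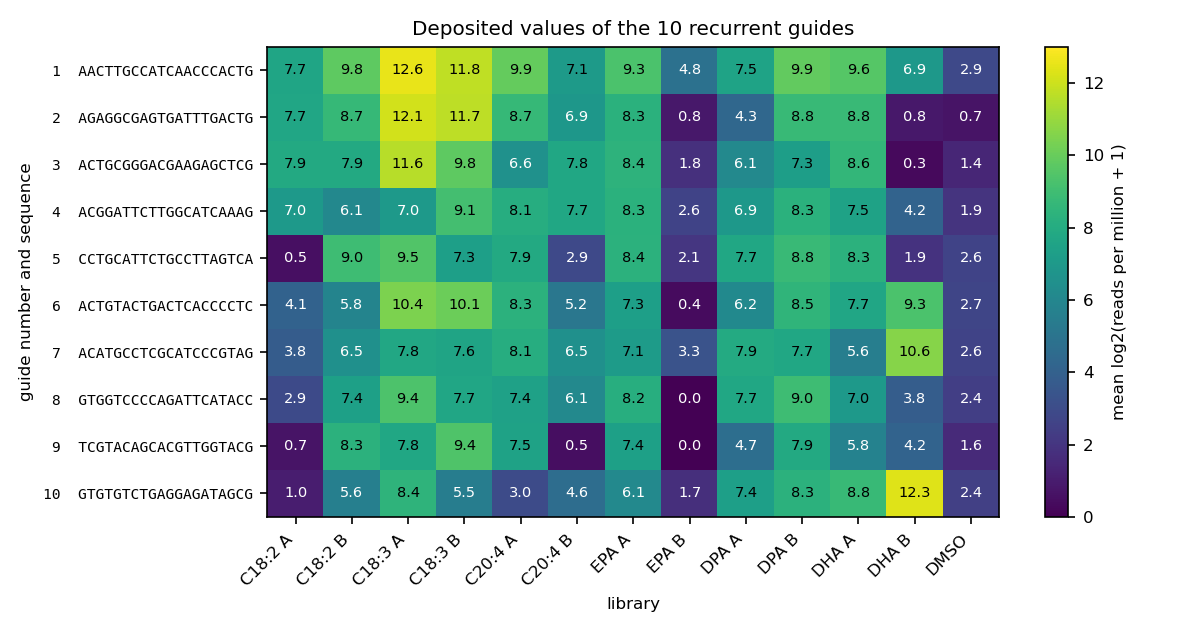
Each cell gives the deposited value, mean log2(RPM + 1), of 1 of the 10 guides in the top 1% of at least 6 ML210 libraries (rows) in each library (columns), with DMSO at the right. Guides 1 to 3 reach 12.59, 12.10 and 11.62 in C18:3 A, and guides 2 and 3 are at 0.82 and 0.32 in DHA B, where guide 10 is at 12.34.

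Chance alone would put a share of 0.05 of the 38067 guides at an unadjusted p under 0.05. Each such count of the main fit among acids, given below, is smaller than that, so these counts are no sign of differences. Some fits without 1 library or without the filter gave more. Among the 6 acids, 0 guides differed in limma's F-test, with 1183 at an unadjusted p under 0.05. That count was 2973 without C20:4 B, 2645 without EPA A, 2232 without DHA A, 731 without DPA B and 4687 with no filter. The 5 guides of smallest p did not pass (adjusted p = 0.988). They were TTCATTGACATAGCCAGGAG and CCAATCGGACACCTACCAGG, highest with DHA at 8.21 ± 2.40 (SD, n = 2) and 8.04 ± 2.84 (SD, n = 2), ATGTAGCAAAGACTGACAGG, highest with C18:2 at 6.52 ± 0.0 (SD, n = 2), and TAATCTGTTCTGGATTGCTA and TCAACATGGTCATTAAACCA, highest with C20:4 at 7.45 ± 1.46 (SD, n = 2) and 6.92 ± 0.67 (SD, n = 2). Over the other 10 libraries, these guides averaged between 0.31 and 1.86.

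The acids of 18 carbons were set against those of 20 and 22. ATGTAGCAAAGACTGACAGG lay between 5.39 and 6.52 in the 4 libraries of C18 acids, with a mean of 6.09 ± 0.55 (SD, n = 4), and between 0 and 4.01 in the other 8, with a mean of 0.91 ± 1.41 (SD, n = 8). CTCCAACCAGTTTCAGACCG averaged 5.77 ± 1.12 (SD, n = 4) and 1.5 ± 1.47 (SD, n = 8). Neither passed in limma (differences of 5.26 and 4.35 on the log2 scale, adjusted p = 0.987), and 0 of 38067 guides did, with 1398 at an unadjusted p under 0.05 (2697 without C18:2 A, 2358 without C18:3 B). Guide 2 averaged 11.91 with C18:3, 8.19 with C18:2 and 7.79 with C20:4, and guide 3 averaged 10.69, 7.9 and 7.15. Both were lower with EPA, DPA and DHA, and C18:2 lay near C20:4. Guides 2 and 3 were higher with C18 acids by 4.2 (95% interval 1.34 to 7.07) and 3.52 (0.90 to 6.14), and intervals for the other 8 named guides included 0 (limma adjusted p = 0.987 for guides 2 and 3). Without both EPA B and DHA B, where guides 2 and 3 were lowest, these differences were 2.75 (0.09 to 5.41) and 2.13 (-0.27 to 4.54). The interval of guide 3 also included 0 without C18:2 B (3.15, -0.01 to 6.31) and without C18:3 A (2.73, -0.36 to 5.82). With 1 library left out, the interval of guide 1 excluded 0 in 5 of 12 fits (differences of 1.48 to 3.29 over the 12), and that of guide 9 excluded 0 without C18:2 A alone (4.19, 0.56 to 7.81). The mean of the 10 guides was 7.62 ± 2.37 (SD, n = 4) with C18 acids and 6.38 ± 2.17 (SD, n = 8) with longer ones, a difference of 1.25 (two-sided exact permutation p = 0.398). Among letter A libraries the difference was -0.47 and among letter B libraries 2.97, and without EPA B and DHA B it was 0.32.

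C18:3 and C18:2 differ by 1 double bond. All 10 named guides were higher with C18:3, by 1.57 to 5.31 on the log2 scale (also without centring and with libraries scaled to equal totals), and the interval of the difference excluded 0 for guide 6 alone (5.31, 95% interval 0.96 to 9.65). That interval included 0 without C18:2 A (3.69, -1.75 to 9.14) and without C18:3 A (4.48, -1.13 to 10.1). Without C18:2 B the intervals of guides 1, 5, 8, 9 and 10 excluded 0 too, and without C18:3 B that of guide 10. Each of these 4 fits leaves a single library in an arm and takes its spread from the other groups, so they decide nothing about single guides. Without C18:2 A, 8 of the 10 were higher after centring and 9 as deposited. For guide 1 the difference was 3.50 (-0.47 to 7.46). The guides of smallest p were AGCTGCCAGGCATAATAGGA, listed at 0 in both C18:3 libraries and at 6.72 ± 0.43 (SD, n = 2) with C18:2, and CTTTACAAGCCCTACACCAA, at 8.82 ± 0.58 (SD, n = 2) with C18:3 and 1.01 ± 1.42 (SD, n = 2) with C18:2. Neither passed (limma adjusted p = 0.974). In all, 0 guides differed and 1562 were at an unadjusted p under 0.05 (2805 without C18:2 A, 2667 without C18:3 B).

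EPA has 1 double bond more than C20:4. Of the 10 named guides 9 were lower with EPA (10 with libraries scaled to equal totals), with the largest difference, -3.37, for guide 2 (95% interval -8.04 to 1.31), and every interval included 0. The direction rested on EPA B: without it, 5 guides were higher and 5 lower with EPA after centring, and 9 higher and 1 lower on the values as deposited. Without C20:4 A, 6 were lower after centring and 7 as deposited. GGGAGAGAGAATTTCGTACG was at 8.09 ± 2.34 (SD, n = 2) with EPA and 0.26 ± 0.37 (SD, n = 2) with C20:4, and TGGAGCGGTTGAAGCAAGGT was listed at 0 in both EPA libraries and at 6.90 ± 1.07 (SD, n = 2) with C20:4 (limma adjusted p = 0.998 for both). The test called 0 guides, with 1633 at an unadjusted p under 0.05 (3916 without C20:4 B, 3050 without EPA A, 1007 without EPA B).

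DHA has 1 double bond more than DPA. Differences for the named guides ran from -2.26 for guide 5 to 3.59 for guide 10 (95% interval -0.89 to 8.08), and every interval included 0. TTCATTGACATAGCCAGGAG and CCAATCGGACACCTACCAGG were listed at 0 in both DPA libraries. Their DHA values ranged from 6.52 to 9.91 and from 6.03 to 10.05, and limma's adjusted p was 1. Here 0 guides passed and 1369 were at an unadjusted p under 0.05 (2300 without DHA A, 807 without DPA B). Without DHA A the count was 740, a fit that leaves DHA B alone in its arm and assumes that it varies like the other groups.

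DPA has 2 carbons more than EPA at the same number of double bonds. All 10 named guides were higher with DPA under each of the same scalings, by 0.71 to 3.40 after centring, and every 95% interval included 0. The direction rested on EPA B: without it, 5 guides were higher and 5 lower with DPA after centring, and 4 higher and 6 lower on the values as deposited. Without DPA B, 8 were higher after centring and 9 as deposited. AGTAATCCCTGACACGACAG was listed at 0 in both DPA libraries and at 6.41 ± 0.72 (SD, n = 2) with EPA, and TGATAGTATCAGCAGTGATG was at 0.18 ± 0.26 (SD, n = 2) with DPA and 6.47 ± 0.99 (SD, n = 2) with EPA (limma adjusted p = 1 for both). There were 0 guides past the threshold and 1594 at an unadjusted p under 0.05 (3123 without EPA A, 962 without EPA B, 922 without DPA B). Without EPA A, which leaves EPA B alone in its arm, the count was 738. For a pair of acids the median width of a guide's 95% interval was 7.54 on the log2 scale, so only very large differences were detectable.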

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

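The alternatives to the limma fit fixed in advance were 2 pseudocounts, 2 filters, 2 scalings, the replicate letter as a block and the 12 fits that leave out an ML210 library. Alternatives to the recurrence test and to comparisons of the named guides, DMSO as a fixed reference, and fits without both EPA B and DHA B were chosen after seeing the data. All 14 counts of guides from limma were 0 under every alternative fixed in advance, with the exception of fits that left 1 narrow library alone in its arm. Leaving out 1 library gave 0 to 740 guides for DHA against DPA (740 without DHA A) and 0 to 738 for DPA against EPA (738 without EPA A). In both, the lone library is assumed to vary like the others. Without both EPA B and DHA B all 14 counts were 0. With DMSO as a fixed reference, 420 guides were enriched and 49 depleted in the pooled comparison and 10 were enriched with C18:3. That fit drops the spread of the DMSO library, and how many of its calls come from this is not known.

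With the replicate letter as a block, 0 guides passed in every comparison. The main fit did not take the letters as pairing the libraries. The 15 correlations of deviations between acids ranged from -0.016 to 0.053, with 0 above 0.1. Libraries of the same acid themselves correlated at only 0.082 to 0.214, so such low values cannot show that the letters do not pair libraries. Top guides were shared more within a letter. The 10 named guides were chosen for being high in these libraries, so their direction against DMSO is no test. All 10 passed with DMSO as a fixed reference and 0 under those fixed in advance. The size of the change moved with the processing. Over the 9 alternatives other than leaving out 1 library, it was 5.2 to 7.55 for guide 1 and 4.66 to 8.77 for guide 2. For guide 3 it was 4.18 to 7.56, and for guide 4 it was 3.7 to 6.58.

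The 27 recurrent guides became 57 without strata of DMSO value (25 of the 27 among them) and 17 with a beta-binomial null, and ranged from 21 to 27 when 1 library was left out. The cause was not tested. The 10 guides in at least 6 libraries became 16 with the top 2% of each library, a wider criterion that includes all 10, and were 9 or 10 when 1 library was left out. The difference of the 10 guides between C18 and longer acids was 0.57 to 2.35 when 1 library was left out, 2.35 without C18:2 A and 0.57 without C18:3 A, and stayed short of the threshold. The mean difference in shared top guides between same-acid and different-acid pairs ranged from -4.3 to 2.28 when 1 library was left out, turning from -2.08 to 2.28 without EPA A, and was -2.72 to 4.36 (0.0 with all 12) when both kinds of pair had different letters. Gene-level alternatives, non-targeting centring, the guide test, edgeR and DESeq2 were not run, as the table gives neither genes nor whole reads. Most guides above 0 were read in 1 of 3 measurements. Their median value there was 0.9 to 3.2 RPM in DHA B, EPA B and C20:4 A, near the worth of a few reads, and 28.6 to 50.6 RPM in the other 9 libraries, where read depth does not account for the missing measurements.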

Other observations

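The tests of starting abundance, of carry-over, of read depth, of pairing by acid and of regroupings for C18 acids were chosen after the results they bear on had been seen. In DHA B guides 10, 7 and 6 were the highest of the named guides, at 12.34, 10.64 and 9.33, while guides 2 and 3 were at 0.82 and 0.32. In C18:3 A the highest were guides 1, 2 and 3, at 12.59, 12.10 and 11.62, and in C18:3 B guides 1, 2 and 6, at 11.75, 11.71 and 10.06. Guide 6 was higher in both C18:3 libraries than in DHA B. The 10 guides together held 4.2% of the linear total of C18:3 A, 2.38% of C18:3 B, 0.87% of DPA B, 0.85% of DHA B and 0.01% of EPA B. In the remaining ML210 libraries they held 0.27% to 0.67%. In EPA A, C18:3 A and DPA B all 10 were in the top 1%. Guides in the top 1% of both libraries of an acid numbered 29 for C18:3, 26 for DPA, 17 for C18:2, 15 for DHA, 11 for C20:4 and 3 for EPA, where chance gives 7.46. Of those 29 for C18:3, 9 were among the 10 named guides, which were chosen in part for being high in these libraries.

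The recurrence of 10 guides in at least 6 of 12 libraries was set against 3 technical explanations. If guides recurred because they started abundant, those that reach 6 libraries when ranked without regard to DMSO value would be abundant in DMSO, yet 9 of those 13 lay below the 90th percentile, down to 14.8. The other 4 lay at or above it, and guides 1, 5, 6 and 7 lay at percentiles 81.3 to 86.4. The test thus speaks only against the highest DMSO values as the whole cause. The 10 named guides were ranked among guides of like DMSO value, which need not be the starting value. Base composition is argued against by 11 guides reaching 6 libraries within classes of GC count and DMSO value. Reads carried over from the library where a guide was highest would bring along the other abundant guides of that library at the same rate. This test had 6 forms (the 20 or 50 most abundant guides, with a tolerance of 1, 4 or 8 times). All were tried after the recurrence was known, with their bounds set after the values were seen. For guides 7 and 10, highest in DHA B, 0.0% to 16.7% of those guides reached the predicted RPM. This argues against carry-over from DHA B for both, and other sources of carry-over were not tested. For the other 8 guides, highest in a C18:3 library, the share was 5.6% to 69.0%. As a further form, the median RPM predicted for the 49 other guides was 6.1 to 38.5 times the observed one for these 8 and 75.9 to 283.6 times for guides 7 and 10. Carry-over is left open for the 8, and from sources other than DHA B for guides 7 and 10. Loss of the targeted gene favouring survival is a candidate explanation and a hypothesis only: cells resistant for another reason before the cultures were split would recur in the same way, and this was not tested.

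The narrowness of EPA B and DHA B was set against read depth. DHA B had more total reads than 8 of the other 11 ML210 libraries, and 2 libraries with fewer reads than EPA B had more guides above 0 and a lower share in the top 1%, so total depth does not account for either. Abundant guides taking the reads of the rest is left open. Sampling the remaining reads at DMSO proportions would detect at least 71.71 percentage points more guides than were seen in these 2 libraries. The same prediction was too high in all 12 ML210 libraries, by 35.1 to 72.12 points, so the gap is not particular to these 2. Treated cells need not keep DMSO proportions, and guides read in only 1 measurement were there at a median of 1 read, which is what a shortage of reads would give. No biological explanation was tested, since the other library of each acid was broad.

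Top guides were shared more between libraries of the same letter, while libraries of the same fatty acid shared no more on average than libraries of different acids. Libraries of different acids shared 21.0 top guides on average with the same letter and 16.83 with different letters, and the real arrangement gave the largest difference, 4.17, with 1 of 32 arrangements as large and 2.30 the highest of the others (one-sided exact p = 0.0312, the smallest possible). With 1 factor fitted per library, 1 of 32 arrangements was again as large (highest other 0.49 against 0.93), which argues against broader libraries sharing more as the whole cause. Same-acid pairs always join an A with a B. They shared 16.83 on average, as did different-acid pairs of an A with a B (16.83), and 390 of 720 ways to pair each A with a B gave as many (highest other mean 21.17). The difference of 0.0 depended on the libraries: it was 4.36 without EPA A and -2.72 without C18:3 A. Letters may mark cultures or a handling batch, which the labels do not say. No biological explanation was tested.

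For C18 against longer acids the real grouping called 0 guides, so all splits of the 12 libraries into 4 and 8 give as many by construction (100 of 100, the highest other 1) and this count says nothing about chance. At an unadjusted p under 0.05 the real grouping gave 1398 guides (2697 without C18:2 A, 2358 without C18:3 B), 61 of 100 splits gave at least as many and the highest other gave 3691, so chance cannot be excluded for that count.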
